A study of Mus musculus with 14 samples.

How the data were processed

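RNA was measured with Affymetrix whole-transcript expression arrays in mouse hematopoietic progenitor cells (HPCs), lineage-negative bone marrow cells that were cultured and then transduced with a retrovirus. The mice were wild type (WT), heterozygous (Het) or homozygous (Hom) for a mutant allele of Polg, the gene of the catalytic subunit of the polymerase that copies mitochondrial DNA (mtDNA). The vector carried either a fluorescent marker alone (Ctrl) or N-Myc with the marker (NMyc). The labels give 14 arrays in 6 groups and call them biological replicates, so the p-values measure the spread between these samples: 3 arrays each for WT-Ctrl and Het-Ctrl, and 2 each for Hom-Ctrl, WT-NMyc, Het-NMyc and Hom-NMyc. RNA was column-purified, amplified, labelled with biotin and hybridised, per the labels' protocols.

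The deposited table holds 1 log2 value per probe set and array, made by the authors with Affymetrix Expression Console, per the submitters' processing notes. Its version, the summary method and the normalization are not given in the sources used here. The log2 scale was read from the values, which ran from 2.24 to 13.5. The arrays' medians lay within 0.198 of each other, and no further scaling was applied. A change that moved most transcripts the same way could have been removed by scaling of this kind before deposit. Pairs of arrays correlated at 0.958 to 0.994 across probe sets. For arrays, their number limits the precision.

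The table has 28846 probe sets. Array control sets (6640) were left out, which left 22206 for testing. The wording fixed for the tests names IDs beginning with AFFX (31 sets) and any set that a probe table marks as a control. The probe table supplied marks none. The other control sets (positive and negative control sets and spike-in mixes) were therefore recognised by their IDs and left out as controls. A count with only the AFFX sets left out, the literal reading, stands beside each count that it moves by more than 1.5 times. Gene symbols came from the platform's annotation, updated through a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Of the tested probe sets, 19572 paired with 1 symbol (19505 distinct symbols), 0 with several, and 2634 were not listed and stay unnamed. For 55 symbols with several probe sets, the set with the highest mean over the 14 arrays was used in gene lists and for named genes.

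Tests used limma 3.58.1 in R 4.3.3. A model with 6 group means was fitted to all 14 arrays with lmFit, and the spread was moderated with eBayes, which left 8 residual degrees of freedom and added 7.3 prior ones. Then 12 differences were tested on both sides: NMyc minus Ctrl averaged over the genotypes and within each, each pair of genotypes within each vector, and the NMyc effect in Het or Hom minus that in WT. P-values were adjusted with the Benjamini-Hochberg method over all tested probe sets of a comparison, and an adjusted p under 0.05 counted as a call. Every adjusted p given for a gene is limma's with this adjustment. Group values are means ± SD, and changes are on the log2 scale with the model's standard error (SE). Where 1 of 2 groups held an array in which the gene was not above the median of the negative control sets, such arrays were put at that median and the difference is given as a bound, with the model's adjusted p.

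Groups of genes were fixed as 40 lists before the data were examined, as were the tests, the alternatives and the rule for naming genes. They hold 983 entries, of which 878 matched a probe set. A list of the genes encoded by mtDNA matched 0 and could not be tested, since the gene table lists none of them by symbol, which left 39. Lists were tested per comparison with limma's camera, which compares a list's genes with all others, at a preset correlation between genes of 0.01 and with adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. At least 3 measured members were required.

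The genes named are, per comparison, up to 10 with the largest rise and 10 with the largest fall among called probe sets with 1 symbol whose groups do not overlap (for the average and for differences of effects, called only). Predicted-gene and clone symbols were left out. Up to 4 members with the smallest p were added per list that was called or held a call, and Mycn, Myc and Polg are always given. Where a comparison had 0 calls, the smallest p-values of each direction could be named as not passing. The Y-linked genes were singled out after their values were seen.

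The sample codes in the labels form 3 runs. Run 1 holds replicate 1 of each Ctrl group, run 2 holds replicate 2 of each Ctrl group with replicate 1 of each NMyc group, and run 3 holds replicate 3 of WT-Ctrl and Het-Ctrl with replicate 2 of each NMyc group. The labels do not call these runs batches. Differences were recomputed within each run. Across genes, deviations from the group means correlated at 0.24, 0.27 and 0.25 between WT-Ctrl and Het-Ctrl arrays of the same replicate number, so these numbers pair the arrays of that comparison, as a hint from the data and not from the labels. With the number as a block that comparison still had 0 calls. Alternatives were the replicate number as a block, the code run as a block, runs 2 and 3 alone, quantile normalization, a filter on dim probe sets, 1 probe set per gene, limma's trend and robust options, each array left out in turn, and, chosen after seeing the data, only the AFFX controls left out.

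The limma fit of each comparison was tested on simulated data over 22206 genes, with known changes in a small share of them and independent noise. Camera was tested on a raised and an unchanged list. The alternatives and the later tests were not simulated. Recovery may differ in the data, where more genes change and genes vary together. Changes of 2-fold were recovered at 100% for the averaged NMyc effect, at 89.55% for Hom minus WT with Ctrl, at 79.1% for Hom minus WT with NMyc and at 37.31% for the difference between the NMyc effects in Hom and WT. At 1.5-fold the same shares were 85.07%, 17.91%, 4.478% and 1.493%.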

Results

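Expression of 22206 probe sets was measured on 14 arrays of mouse HPCs from 3 Polg genotypes, each transduced with the Ctrl or the NMyc vector. Groups held 3 arrays (WT-Ctrl, Het-Ctrl) or 2 (Hom-Ctrl, WT-NMyc, Het-NMyc, Hom-NMyc), and this number limits the precision. The series was set up to follow the expression changes that come with N-Myc and with mtDNA mutations that build up in Polg mutant cells. Positive control sets stood above negative ones by 3.963 ± 0.186 log2 units with Ctrl (SD, n = 8) and by 4.362 ± 0.188 with NMyc (SD, n = 6). Along the first principal component, which held 54.4% of the variance, the Ctrl arrays lay between -40.7 and -20.2 and the NMyc arrays between 37 and 43.9. The second (10.2%) set the Hom-Ctrl arrays apart at -27.1 and -37.5.

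**Figure D1:**
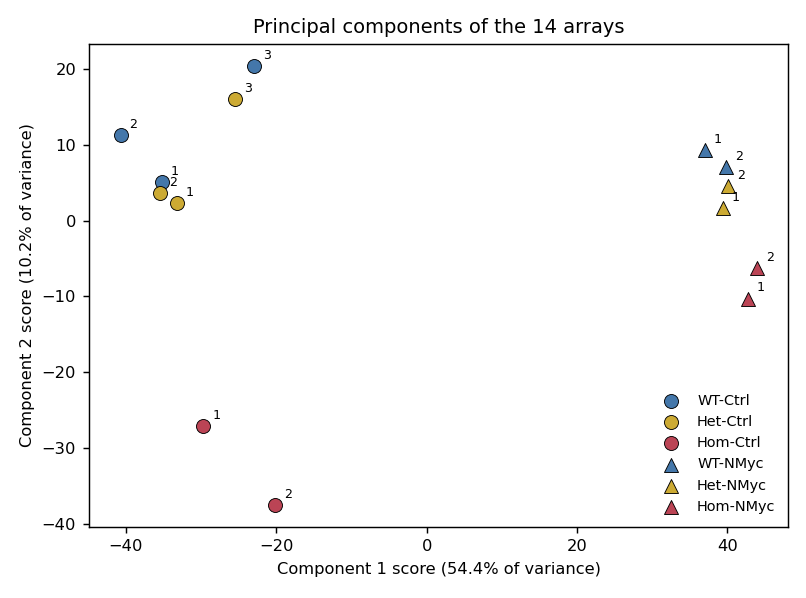
Position of each of the 14 arrays on the first and second principal components of the log2 values (arbitrary units), with colour and symbol for genotype and vector and a point per array. The vectors separate along the first component (54.4% of the variance), and the Hom-Ctrl arrays lie lowest on the second at -27.1 and -37.5.

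Mycn, the transduced gene, was read first in every array as a check of the labels. Its value was 7.43 to 7.76 in the WT-Ctrl arrays, 7.50 to 7.65 in the Het-Ctrl arrays and 12.15 to 12.38 in the NMyc arrays. Of the Hom-Ctrl arrays, replicate 2 read 7.61 and replicate 1 read 9.77, above every other Ctrl array and below every NMyc array. Averaged over the genotypes Mycn rose by 4.31 with NMyc (SE 0.23, 19.8-fold, adjusted p = 2.64e-09), and by 4.64 in WT, 4.65 in Het and 3.64 in Hom. Myc, the related proto-oncogene, fell by 1.32 (SE 0.10, 2.49-fold, adjusted p = 4.51e-08). Polg was 0.30 higher with NMyc (SE 0.11, adjusted p = 0.0488), a call that 17 of 22 alternative settings did not give (adjusted p up to 0.209, with the code run as a block). A transcript level does not check a Polg genotype that differs by a mutation, so the genotype labels rest on the submitters.

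The first question was what N-Myc does to expression in HPCs. Machinery for making ribosomes rose most: of 48 measured members of the ribosome biogenesis list 47 rose and 0 fell, with a median of 1.22. Dkc1, the pseudouridine synthase of ribosomal RNA, rose by 2.24 (SE 0.19, 4.73-fold, adjusted p = 2.15e-07). Polr1b, a subunit of RNA polymerase I, rose by 2.05 (SE 0.12) and Utp20, a factor of small-subunit processing, by 1.99 (SE 0.13). Hsph1, a heat shock protein, rose by 2.30 (SE 0.16), and Dctd, the deoxycytidylate deaminase, by 2.17 (SE 0.11). Fastkd2, a mitochondrial RNA-binding protein, rose by 2.16 (SE 0.15). Among the largest falls, Mmp12, the macrophage elastase, fell by 4.38 (SE 0.27, 20.9-fold, adjusted p = 9.58e-09). Ppbp, a platelet chemokine, fell by 4.27 (SE 0.17), Tpsb2, a mast cell tryptase, by 3.77 (SE 0.08), and Gzmb, a cytotoxic granule protease, by 3.20 (SE 0.13). In all, 7470 probe sets were called by limma for the averaged effect, 4032 up and 3438 down, of which 617 and 613 changed at least 2-fold.

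Growth lists were tested with camera, and the first count of members is over all genes tested, the second adjusted over the list alone. Ribosome biogenesis rose in 47 of 48 members on both counts (adjusted p = 8.77e-32), with Ddx18, a nucleolar helicase, up by 1.68. Translation factors rose in 16 of 19 members (17 adjusted over the list alone, median 0.60, adjusted p = 8.49e-10, and adjusted p = 0.0715 with an estimated correlation). Among 39 cytosolic ribosomal proteins 1 rose and 1 fell (0 and 0 adjusted over the list alone), with a median of 0.03 and adjusted p = 0.741, but 27 of the 39 lay above the 99th percentile of all values (11.9), where a change could be compressed. The nucleotide synthesis list rose in 18 of 22 members on both counts (median 0.83, adjusted p = 3.55e-11), among them Cad, which opens pyrimidine synthesis, by 1.63 and Gart of purine synthesis by 1.57. Serine, one-carbon and glutamine genes rose in 13 of 18 and fell in 1 (14 and 1 adjusted over the list alone, median 0.71, adjusted p = 2.06e-07, and adjusted p = 0.0903 with an estimated correlation). DNA replication genes rose in 33 of 38 and fell in 1 (34 and 1, median 0.75, adjusted p = 1.08e-13, and adjusted p = 0.118 with an estimated correlation), with Mcm2, a subunit of the replicative helicase, up by 1.25. Fatty acid and sterol synthesis rose in 12 of 23 (15 adjusted over the list alone, median 0.40, adjusted p = 1.59e-05, and adjusted p = 0.163 with an estimated correlation), led by Fasn, the fatty acid synthase, at 1.78. Mitosis genes rose in 13 of 28 and fell in 2 (14 and 2, median 0.21, adjusted p = 0.00567, and adjusted p = 0.447 with an estimated correlation); quantile normalization ended that call (adjusted p = 0.126).

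Several lists of nuclear genes of mitochondria rose with NMyc as well, while mitochondrial dynamics and mitophagy (adjusted p = 0.455) and fatty acid oxidation (0.0584) were not called. The mitochondrial ribosome rose in 69 of 75 members and fell in 1 (71 and 1 adjusted over the list alone, median 0.65, adjusted p = 1.25e-24), with Mrpl12 up by 1.36. Complex I of the respiratory chain rose in 26 of 35 and fell in 1 (27 and 1, median 0.60, adjusted p = 4.78e-10, and adjusted p = 0.0635 with an estimated correlation). Complex III rose in 7 of 9 on both counts (median 0.53, adjusted p = 4.77e-05), and complex V, the ATP synthase, in 13 of 15 (15 adjusted over the list alone, median 0.49, adjusted p = 1.27e-07). Complex IV rose in 9 of 11 and fell in 1 on both counts (median 0.39, adjusted p = 0.00225, and adjusted p = 0.092 with an estimated correlation), the exception being Cox7a2l, an assembly factor of supercomplexes, at -0.83. TCA cycle genes rose in 17 of 21 and fell in 1 on both counts (median 0.62, adjusted p = 9.81e-09, and adjusted p = 0.0715 with an estimated correlation), with Idh3a at 1.47. Mitochondrial chaperones and proteases rose in 15 of 17 and fell in 1 on both counts (median 0.70, adjusted p = 9.94e-09), with Hspd1 at 1.59. Genes of mtDNA maintenance and transcription rose in 11 of 19 and fell in 4 (12 and 4 adjusted over the list alone, median 0.30, adjusted p = 0.00455, and adjusted p = 0.207 with an estimated correlation), among them Twnk, the mtDNA helicase, at 0.97 and Polrmt, the mitochondrial RNA polymerase, at 0.84. Antioxidant genes rose in 13 of 21 and fell in 3 (14 and 4, median 0.33, adjusted p = 0.00322), with Prdx3 of mitochondria at 0.91. Of the lists in this paragraph, those for complexes III and V, the mitochondrial ribosome, chaperones and antioxidants kept their call with an estimated correlation (adjusted p of 0.0387, 0.0202, 0.0387, 0.0387 and 0.0387).

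Several blood lineage lists and the inflammatory list fell, while the erythroid, B lymphoid and stem and progenitor lists were not called (adjusted p = 0.787, 0.65 and 0.361). The megakaryocyte and platelet list fell in 16 of 17 members (17 adjusted over the list alone, median -1.55, adjusted p = 3.22e-15), with Pf4, a platelet chemokine, at -2.75. Inflammatory cytokine and NF-kB genes fell in 20 of 25 on both counts (median -1.2, adjusted p = 2.95e-11, and adjusted p = 0.0822 with an estimated correlation), among them Il6 at -2.51 and Il1b at -2.63. Neutrophil granule genes fell in 15 of 24 and rose in 4 on both counts (median -0.51, adjusted p = 1.40e-06, and adjusted p = 0.0843 with an estimated correlation), with Mmp9 at -3.05 and Ltf, lactoferrin, at -2.02. Monocyte, macrophage and dendritic genes fell in 15 of 25 (15 with 1 rise adjusted over the list alone, median -0.52, adjusted p = 2.60e-06, and adjusted p = 0.09 with an estimated correlation), with Lyz2, a lysozyme, at -2.09. Mast cell and basophil genes fell in 13 of 19 and rose in 1 (15 and 2, median -0.51, adjusted p = 1.34e-05, and adjusted p = 0.0715 with an estimated correlation). Eosinophil genes fell in 4 of 8 and rose in 1 (median -0.51, adjusted p = 0.0169, and adjusted p = 0.0777 with an estimated correlation), with Epx, the eosinophil peroxidase, at -2.01. T and NK genes fell in 4 of 17 (median -0.11, adjusted p = 0.0231, and adjusted p = 0.09 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.0607) and without WT-NMyc replicate 2. These shifts accompanied the higher contrast of positive over negative control sets on NMyc arrays given above.

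Interferon response genes fell in 15 of 30 and rose in 2 (16 and 2 adjusted over the list alone, median -0.35, adjusted p = 2.86e-05), with Ddx58, a sensor of viral RNA, at -1.42. The MYC-repressed and network list fell in 16 of 24 and rose in 2 (median -0.75, adjusted p = 6.08e-07), with Cdkn1b, an inhibitor of cell cycle kinases, at -1.49 and Cdkn2a at -1.89. Hypoxia genes fell in 8 of 18 (median -0.39, adjusted p = 0.00175, and adjusted p = 0.415 with an estimated correlation), with Ndrg1 at -1.39. Apoptosis genes fell in 10 of 24 and rose in 5 (11 and 5 adjusted over the list alone, median -0.21, adjusted p = 0.0243, and adjusted p = 0.0843 with an estimated correlation), among them Bcl2a1b, an antiapoptotic relative of Bcl2, at -2.04. Targets of p53 fell in 11 of 23 and rose in 6 (median -0.21, adjusted p = 0.0345, and adjusted p = 0.487 with an estimated correlation), with Btg2 at -2.19; the code run as a block ended that call (adjusted p = 0.14), as did leaving out WT-Ctrl replicate 1 or Het-NMyc replicate 2. With an estimated correlation, 10 of the 28 list calls for the averaged effect held.

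The other lists did not pass for the averaged effect. They were mitochondrial dynamics and mitophagy (adjusted p = 0.455), glycolysis (0.202), polyamine synthesis (0.174), fatty acid oxidation (0.0584), the ATF4 and mitochondrial stress response (0.0908), stem and progenitor (0.361), erythroid (0.787), B lymphoid (0.65), stromal and endothelial (0.135) and the Y-linked genes (0.361). Single members were called in several of them. Srm, the spermidine synthase, rose by 1.89 and Slc16a1, a lactate transporter, by 1.78, while Slc2a3, a glucose transporter, fell by 1.67. Ddit3, a transcription factor of the stress response, fell by 2.33. Among stem cell genes Slamf1 fell by 1.55 and Meis1 by 1.29. In the B lymphoid list the median was 0.02 while the test pointed down.

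**Figure D2:**
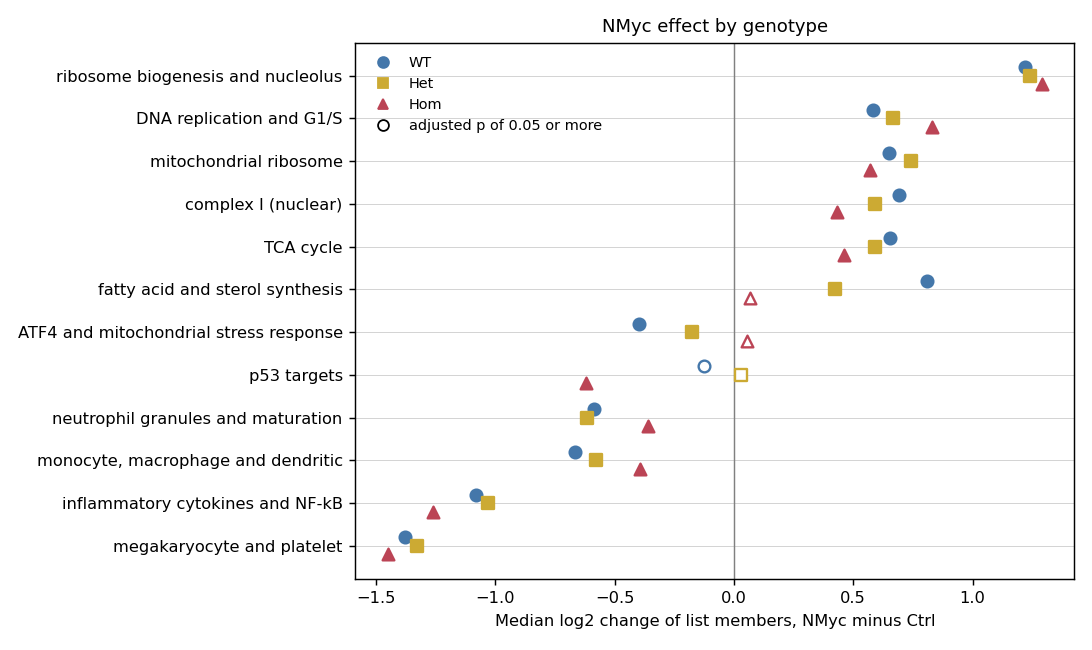
Median log2 change of the members of 12 gene lists with NMyc against Ctrl (horizontal axis, log2 units), with a symbol per genotype, open where camera's adjusted p was 0.05 or more. Ribosome biogenesis lies highest at 1.22, 1.24 and 1.29, and the megakaryocyte and platelet list lowest at -1.38, -1.33 and -1.45.

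Within the genotypes the same question was asked for WT, Het and Hom cells. Mmp12 fell by 4.53 in WT, 4.41 in Het and 4.21 in Hom, and Dkc1 rose by 2.2, 2.28 and 2.24. The ribosome biogenesis list had medians of 1.22, 1.24 and 1.29, and held with an estimated correlation (adjusted p of 0.0286, 0.0286 and 0.0426). The mitochondrial ribosome had 0.65, 0.74 and 0.57, with adjusted p of 0.0402, 0.0382 and 0.0957 with an estimated correlation, so that the call in Hom was lost there. Complex I had 22, 17 and 11 of 35 members up (26, 25 and 15 adjusted over the list alone), with medians of 0.69, 0.59 and 0.43 and adjusted p of 0.0402, 0.0582 and 0.156 with an estimated correlation, which kept the call in WT alone. P53 targets were called in Hom alone (0 up and 10 down of 23, median -0.62, adjusted p = 7.32e-07, and adjusted p = 0.163 with an estimated correlation). The ATF4 list fell in WT (0 up and 9 down of 24, median -0.40, adjusted p = 1.02e-05, and adjusted p = 0.0883 with an estimated correlation) and, less clearly, in Het (2 up and 5 down, adjusted p = 0.0386, and adjusted p = 0.396 with an estimated correlation), a call that 5 of 22 alternative settings did not give (adjusted p up to 0.221, with the replicate number as a block), and was not called in Hom (8 up and 3 down, adjusted p = 0.31). There Cth, an enzyme of cysteine synthesis, rose by 2.08 (SE 0.26, adjusted p = 8.85e-05) and Chac1, which degrades glutathione, by 0.82 (SE 0.18, adjusted p = 0.00476).

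Limma called 4250 probe sets in WT (2240 up, 2010 down), 4232 in Het (2456, 1776) and 3924 in Hom (2367, 1557). Of these, 1458 rose and 876 fell in all 3 genotypes. Each genotype has its own Ctrl arrays, so no array is shared between the effects. The groups do share code runs, and WT-Ctrl and Het-Ctrl arrays of the same number deviated together (r of 0.24, 0.27 and 0.25). Part of the agreement between WT and Het may come from this. WT and Het shared 1859 rises (248 would come from independent lists) and 1417 falls (161), with r = 0.873 across probe sets. For WT and Hom these were 1578 (239), 1013 (141) and 0.756, and for Het and Hom 1700 (262), 975 (125) and 0.789. Probe sets are not independent replicates, and the mean r of 0.806 was 0.744 with only AFFX controls left out. Each count depended on the arrays of its own groups: WT had 2660 and 2380 without WT-NMyc replicates 1 and 2, Het 2504 and 2490 without Het-NMyc replicates 1 and 2. Hom had 2396 without Hom-Ctrl replicate 1, 2365 and 1987 without Hom-NMyc replicates 1 and 2, and 2597 with code runs 2 and 3 alone. Runs 2 and 3 alone leave Hom-Ctrl replicate 2 as the lone Hom-Ctrl array. Between runs 2 and 3 the effect correlated across probe sets at 0.69 in WT and 0.75 in Het.

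Another question was what the Polg genotype changes without N-Myc. In Hom-Ctrl cells, targets of p53 were higher than in WT-Ctrl cells (11 of 23 members called) and neutrophil granule genes lower (7 of 24), with adjusted p = 0.158 with an estimated correlation for the first and adjusted p = 0.147 with an estimated correlation for the second. Eda2r, a receptor of the TNF family induced by p53, was at 6.58 in Hom-Ctrl (n = 2) and 4.43 ± 0.47 in WT-Ctrl (SD, n = 3), where 2 of the 3 arrays were not above the negative control sets, a rise of at least 1.77 (3.41-fold, adjusted p = 0.000321). Zmat3, a p53-induced zinc finger gene, rose by 1.78 (SE 0.26, adjusted p = 0.00211), Cdkn1a, the cell cycle inhibitor p21, by 1.33 (SE 0.18, 2.51-fold, adjusted p = 0.00166) and Phlda3, an inhibitor of Akt, by 1.34. Ptgds, a prostaglandin synthase not above the negative control sets in WT-Ctrl, rose by at least 1.31 (adjusted p = 0.000321) and Mtap, an enzyme of methionine salvage, by 1.57 (SE 0.17, adjusted p = 0.000325). Clec5a, a myeloid lectin receptor, fell by 2.49 (SE 0.34, adjusted p = 0.00157), F13a1, a coagulation factor of monocytes, by 1.69 (adjusted p = 0.000336) and Ltf by 1.42 (SE 0.17, adjusted p = 0.000585). Chac1 fell by 1.2 (adjusted p = 0.00157) and Vldlr, a lipoprotein receptor of the ATF4 list, by 0.94. Mycn (1.10, adjusted p = 0.138) and Polg (-0.26, adjusted p = 0.539) did not pass.

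**Figure D3:**
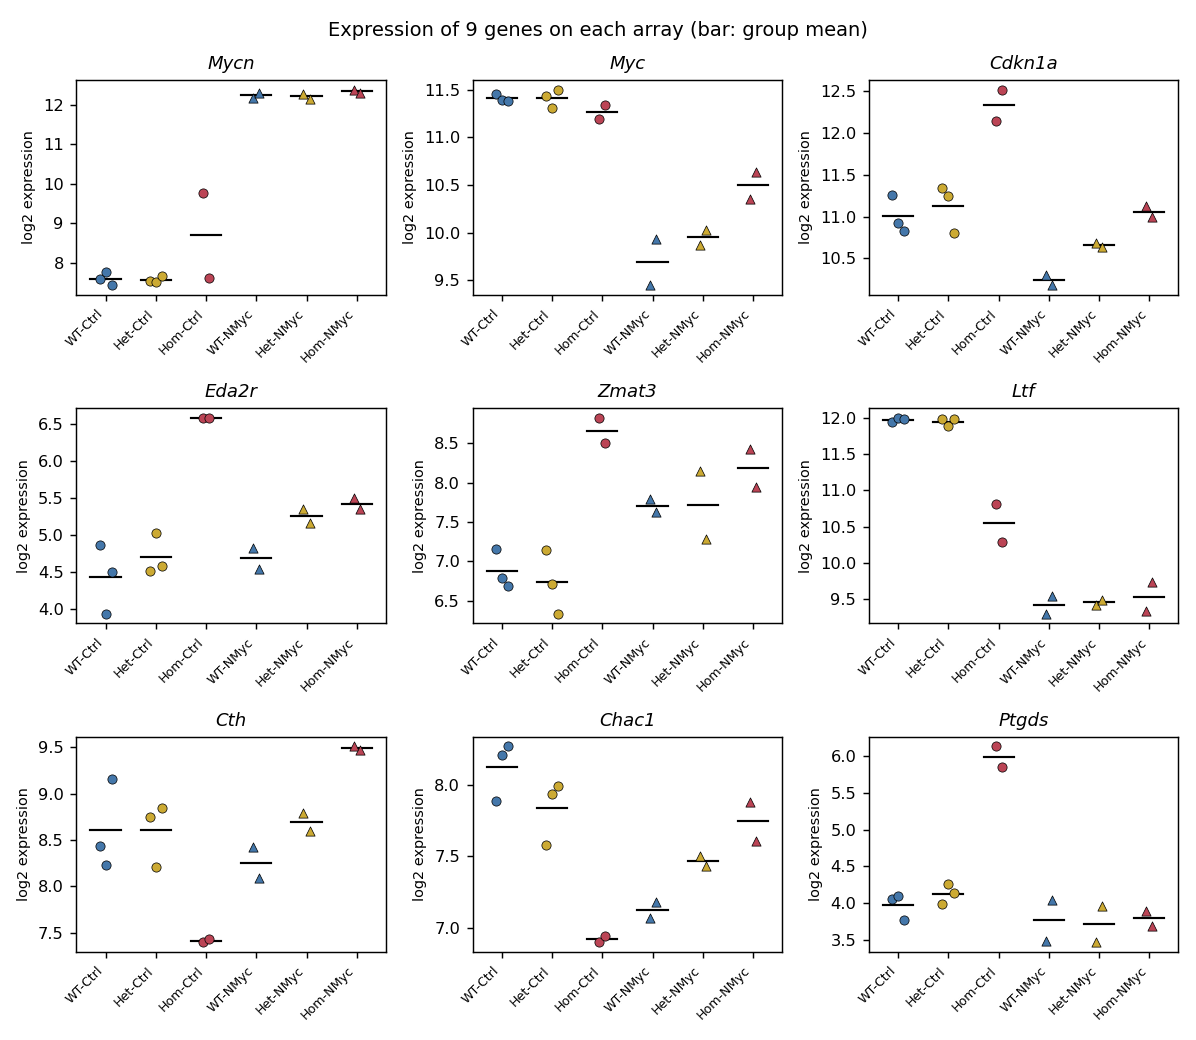
Log2 expression of 9 genes (vertical axes, log2 units) on each of the 14 arrays (points) with the mean of each genotype and vector group (horizontal bars). Mycn lies at 12.15 to 12.38 in the NMyc arrays and at 9.77 in Hom-Ctrl replicate 1, and Eda2r averages 6.58 in Hom-Ctrl against 4.43 in WT-Ctrl.

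Among the lists, p53 targets rose in 11 of 23 members with Hom-Ctrl against WT-Ctrl (16 up and 2 down adjusted over the list alone, median 0.81, adjusted p = 7.78e-10, and adjusted p = 0.158 with an estimated correlation). Neutrophil granule genes fell in 7 of 24 (12 adjusted over the list alone, median -0.30, adjusted p = 1.94e-08, and adjusted p = 0.147 with an estimated correlation), and the ATF4 list in 6 of 24 (10 adjusted over the list alone, median -0.42, adjusted p = 1.32e-08, and adjusted p = 0.147 with an estimated correlation). Antioxidant genes rose in 4 of 21 (9 adjusted over the list alone, median 0.34, adjusted p = 3.76e-06), among them Gsta4, a glutathione transferase, by 0.89. It was the single list that kept its call with an estimated correlation (adjusted p = 0.0233). TCA cycle genes rose in 2 of 21 (9 adjusted over the list alone, median 0.36, adjusted p = 2.71e-06, and adjusted p = 0.202 with an estimated correlation), and fatty acid and sterol synthesis in 3 of 23 (8 adjusted over the list alone, median 0.28, adjusted p = 3.46e-06, and adjusted p = 0.25 with an estimated correlation). Complexes I, III, IV and V rose with medians of 0.24, 0.37, 0.32 and 0.31 (2, 1, 2 and 0 members called), which gave adjusted p of 0.238, 0.147, 0.158 and 0.147 with an estimated correlation. Further shifts were called for the mitochondrial ribosome (0.13), polyamine synthesis (0.37), mast cells (0.15), hypoxia (-0.36), DNA replication (-0.23) and monocytes (-0.11), with adjusted p of 0.703, 0.158, 0.356, 0.717, 0.721 and 0.576 with an estimated correlation. Each of these 6 calls was lost without 1 array or more: WT-Ctrl replicate 2 (mitochondrial ribosome, adjusted p = 0.419; polyamine synthesis, 0.0803; hypoxia, 0.296), WT-Ctrl replicate 3 (DNA replication, 0.366) or Hom-Ctrl replicate 2 (mast cells, 0.066; monocytes, 0.655).

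The count for Hom minus WT with Ctrl was 868 (450 up, 418 down), of which 115 and 137 changed at least 2-fold, and 442 with only AFFX controls left out. It was 99 without Hom-Ctrl replicate 2, the array furthest from the other Ctrl arrays (63 probe sets over 1.5 log2 units away, against 3 to 21 for the other 7 Ctrl arrays), and 472 without WT-Ctrl replicate 3. Mmp8, a neutrophil collagenase (-1.13), and Mrc1, a macrophage mannose receptor (-2.81), then missed the threshold without Hom-Ctrl replicate 2 (adjusted p = 0.0701 and 0.2). Within code runs 1 and 2 the p53 list had medians of 0.40 and 0.72, neutrophil granules -0.34 and -0.37, the ATF4 list -0.31 and -0.39, and antioxidants 0.32 and 0.27. Across probe sets the differences of these runs, which share no array, correlated at 0.30. With the code run as a block the count was 984.

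Hom-Ctrl was also set against Het-Ctrl. Zmat3 rose by 1.92, Phlda3 by 1.85 (adjusted p = 0.00065) and Eda2r, above the negative control sets in 1 of 3 Het-Ctrl arrays, by at least 1.84, and Ltf fell by 1.40. P53 targets rose in 13 of 23 members (14 adjusted over the list alone, median 0.78, adjusted p = 2.50e-13, and adjusted p = 0.22 with an estimated correlation). Neutrophil granule genes fell in 8 of 24 (14 adjusted over the list alone, median -0.40, adjusted p = 1.92e-12, and adjusted p = 0.126 with an estimated correlation), and antioxidants rose in 2 of 21 (6 adjusted over the list alone, median 0.32, adjusted p = 3.15e-05, and adjusted p = 0.0339 with an estimated correlation). Mast cell genes rose in 6 of 19 (7 with 1 fall adjusted over the list alone, median 0.26, adjusted p = 4.11e-05, and adjusted p = 0.241 with an estimated correlation). In all 10 lists rose and 4 fell, of which the antioxidant list alone kept its call with an estimated correlation. Limma called 533 probe sets (297 up, 236 down), 231 with only AFFX controls left out, 354 with runs 2 and 3 alone and 884 with limma's trend and robust options. It called 55 without Hom-Ctrl replicate 2, again the array that stood furthest apart, 339 without Het-Ctrl replicate 1 and 163 without Het-Ctrl replicate 3. Runs 2 and 3 alone leave Hom-Ctrl replicate 2 as the lone Hom-Ctrl array, assumed to vary like the other groups. Hom minus Het shared 432 probe sets in the same direction with Hom minus WT. Part of these may come from the Hom-Ctrl arrays that both comparisons use.

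**Figure D4:**
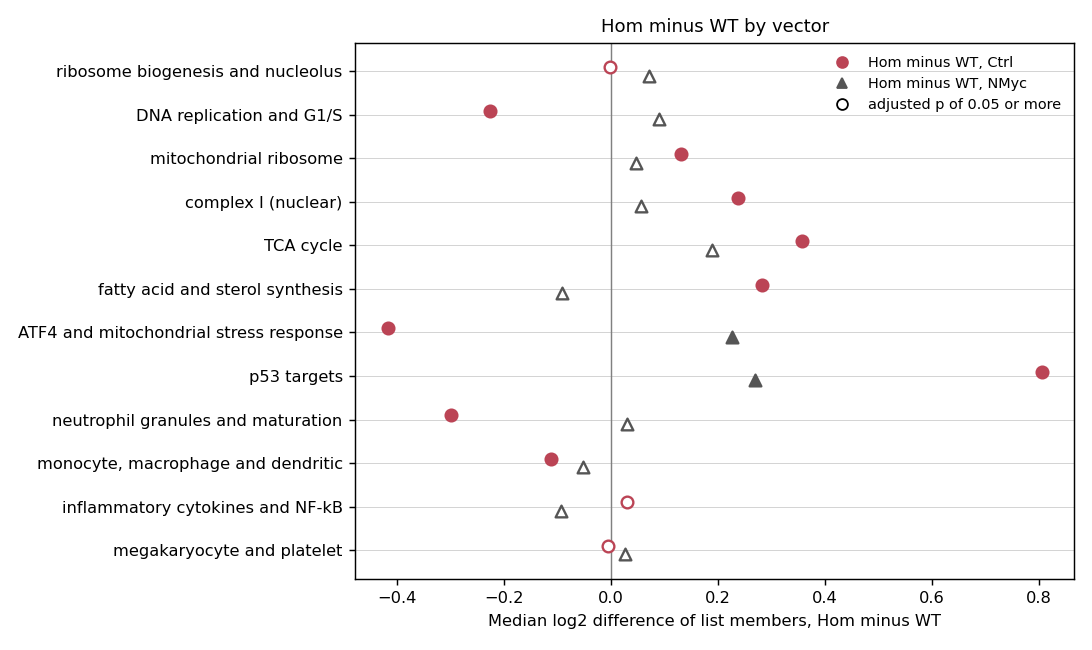
Median log2 difference of the members of 12 gene lists between Hom and WT cells (horizontal axis, log2 units), with a circle for Ctrl and a triangle for NMyc, open where camera's adjusted p was 0.05 or more. The p53 targets lie at 0.81 with Ctrl and 0.27 with NMyc, and the ATF4 list at -0.42 and 0.23.

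Limma called 0 probe sets between Het-Ctrl and WT-Ctrl cells, with 935 at an unadjusted p under 0.05. The smallest adjusted p was 0.878, which Defb26 (-0.72) and Pld4 (-0.97) both had. In the simulated data this comparison recovered 94.03% of 2-fold changes but 31.34% of 1.5-fold ones, so smaller differences could be missed. Fatty acid and sterol synthesis had a median of 0.22 and was called up by camera (adjusted p = 2.88e-08, and adjusted p = 0.875 with an estimated correlation), with 0 of 23 members called on either count. Complex I was called up (0.12, adjusted p = 0.0036, and adjusted p = 0.875 with an estimated correlation), the ATF4 list down (-0.20, adjusted p = 0.0036, and adjusted p = 0.875 with an estimated correlation) and inflammatory genes down (-0.14, adjusted p = 0.0238, and adjusted p = 0.925 with an estimated correlation). Calls were lost without Het-Ctrl replicate 1 for complex I (adjusted p = 0.332), WT-Ctrl replicate 3 for the ATF4 list (0.439) and WT-Ctrl replicate 2 for inflammatory genes (0.457). Between the code runs, this difference correlated across probe sets at -0.05, -0.01 and 0.05.

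With the NMyc vector limma called 0 probe sets between any pair of genotypes, and the comparisons rest on gene lists. The contrast of positive over negative control sets also differed between these groups (4.192 in WT-NMyc, 4.375 in Het-NMyc and 4.52 in Hom-NMyc on average), so genotype and this sign of array quality moved together. Antioxidant genes were 0.26 higher in Hom-NMyc than in WT-NMyc by their median (adjusted p = 0.000461, and adjusted p = 0.0665 with an estimated correlation), with 0 of 21 members called and 2 adjusted over the list alone. P53 targets (0.27, adjusted p = 0.00317, and adjusted p = 0.97 with an estimated correlation) and the ATF4 list (0.23, adjusted p = 0.00317, and adjusted p = 0.97 with an estimated correlation) were called up, with 2 and 4 members adjusted over the list alone. Mast cell genes (0.27, adjusted p = 0.000461, and adjusted p = 0.599 with an estimated correlation) and fatty acid oxidation (0.17, adjusted p = 0.0404, and adjusted p = 0.97 with an estimated correlation) were called up too. The p53 call was lost without Hom-NMyc replicate 1 or dim probe sets (adjusted p up to 0.0552) and that of fatty acid oxidation with quantile normalization (adjusted p = 0.526) and without either Hom-Ctrl array, WT-NMyc replicate 1 or Hom-NMyc replicate 2. Serpinb10 (1.14) had the smallest adjusted p, 0.127, so limma called 0 probe sets, with 1873 at an unadjusted p under 0.05. Between code runs 2 and 3 this difference correlated at 0.38 across probe sets. Hom minus Het gave 0 calls (1093 at an unadjusted p under 0.05) and 1 without Hom-NMyc replicate 1, and Het minus WT 0 (576 at an unadjusted p under 0.05). Against Het, mast cell genes (0.31, adjusted p = 0.559 with an estimated correlation) and antioxidants (0.17, adjusted p = 0.18 with an estimated correlation) were called up and sterol synthesis down (adjusted p = 0.00405, and adjusted p = 0.936 with an estimated correlation), and all 3 calls were lost without Hom-NMyc replicate 2 (adjusted p = 0.0999 for antioxidants) and 2 of them without Het-NMyc replicate 2 (adjusted p = 0.204 for both). Between Het and WT the ATF4 list was called up (0.15, adjusted p = 0.0337, and adjusted p = 0.963 with an estimated correlation), but not without WT-NMyc replicate 1 (adjusted p = 0.618) or Het-NMyc replicate 1.

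Whether the response to N-Myc depends on the genotype was tested as a difference of effects. The NMyc effect on the ATF4 list was higher in Hom than in WT, where the list fell (adjusted p = 0.0883 with an estimated correlation), with 3 of 24 members called (12 adjusted over the list alone, median 0.69, adjusted p = 2.66e-13, and adjusted p = 0.172 with an estimated correlation). Its called members were Cth (2.44, SE 0.36, adjusted p = 0.0147), Chac1 (1.82, SE 0.24, adjusted p = 0.0131) and Vldlr (1.48, SE 0.19, adjusted p = 0.0131). Ltf of the neutrophil list fell less with NMyc in Hom than in WT (1.53, SE 0.25, adjusted p = 0.0318), from Ctrl means of 10.55 in Hom and 11.98 in WT to NMyc means of 9.54 and 9.42. Ptgds was called the other way (adjusted p = 0.0147), but in 3 of the 4 groups it was not above the negative control sets, so no size is given. Neutrophil granules were higher by 0.45 (1 of 24 members called, 6 adjusted over the list alone; adjusted p = 6.97e-07, and adjusted p = 0.339 with an estimated correlation). Sterol synthesis was lower by its median of -0.51 (0 of 23 called, 3 adjusted over the list alone; adjusted p = 2.11e-09, and adjusted p = 0.339 with an estimated correlation), as were p53 targets at -0.39 (0 of 23, 1 adjusted over the list alone; adjusted p = 2.64e-05, and adjusted p = 0.477 with an estimated correlation). Mycn (-1.0, adjusted p = 0.662) and Myc (0.95, adjusted p = 0.183) did not pass. A difference of effects also takes in the genotype difference with Ctrl. For neutrophil granules the median of Hom minus WT was -0.30 with Ctrl and 0.03 with NMyc, and for p53 targets 0.81 and 0.27. For both lists the larger part thus lay with Ctrl. By their medians the same held for the ATF4 list (-0.42 with Ctrl and 0.23 with NMyc) and for sterol synthesis (0.28 and -0.09). Of the 24 neutrophil members, 7 lay above 11.9, the 99th percentile of all values, where a difference could be compressed.

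The test of Hom minus WT effects called 18 probe sets, 16 up and 2 down, with 5 when only AFFX controls were left out, 31 without dim probe sets and 62 with limma's trend and robust options. This count rested on single arrays. It was 0 without WT-NMyc replicate 1, WT-NMyc replicate 2 or Hom-NMyc replicate 2 and 1 without Hom-NMyc replicate 1, settings in which a lone array is assumed to vary like the other groups. Without WT-Ctrl replicate 1 or Hom-Ctrl replicate 1 it was 33, without WT-Ctrl replicate 2 or Hom-Ctrl replicate 2 it was 10, without WT-Ctrl replicate 3 it was 8, and without Het-NMyc replicate 1 or 2 it was 11. For Het minus WT effects limma called 0, with 730 at an unadjusted p under 0.05. There the ATF4 list (0.32), p53 targets (0.27) and serine genes (0.19) were called up and sterol synthesis down (-0.15), each with adjusted p = 0.986 with an estimated correlation and 0 members called.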

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

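The tests of other splits of the arrays, of admixed cells, of run 1 behind the NMyc calls, of fewer arrays with NMyc and of fewer neutrophil cells were chosen only after the result was seen. That of fewer arrays replaced a test set beforehand, the ratio of NMyc to Ctrl differences in run 2 (0.145), because it compared single arrays. That of fewer neutrophil cells replaced one of p53 targets against other markers (0.8 apart), which those markers, going both ways, did not settle. The following came to attention because the NMyc effect differed between genotypes by a test of the difference itself. Against WT, 18 probe sets differed in Hom. Among them were Cth (2.44), Bcl2a1d (1.99), Bcl2a1b (1.88), Nxpe5 (1.86), Ipcef1 (1.83), Chac1 (1.82), Siglecf (1.72), Gpr141 (1.71), Rps6kc1 (1.68), Lrrk2 (1.65), Ltf (1.53) and Vldlr (1.48) above 0, and Ptgds (adjusted p = 0.0147) and Slc28a1 (adjusted p = 0.0483) below. The last 2 had arrays not above the negative control sets in 3 of their 4 groups, so no size is given. For Ltf, Lrrk2 and Ipcef1 the means of WT and Hom were close with NMyc and apart with Ctrl. Lrrk2 was at 5.03 in WT and 4.88 in Hom with NMyc, and at 7.35 and 5.54 with Ctrl. The means of Cth lay apart with both vectors (8.25 and 9.49 with NMyc, 8.61 and 7.41 with Ctrl). With NMyc, however, limma called 0 probe sets between Hom and WT. Bcl2a1b and Bcl2a1d are near-identical copies, so their probe sets are not separate evidence; without Hom-NMyc replicate 2 the count was 0. By their medians, the ATF4 list (0.69), neutrophil granules (0.45), DNA replication (0.26), serine, one-carbon and glutamine (0.24) and monocytes (0.07) lay higher in Hom, with adjusted p of 0.172, 0.339, 0.679, 0.477 and 0.595 with an estimated correlation. Sterol synthesis (-0.51), p53 targets (-0.39), complex III (-0.23), complex IV (-0.23), complex I (-0.22), the TCA cycle (-0.21), complex V (-0.14), the mitochondrial ribosome (-0.13) and cytosolic ribosomal proteins (-0.13) lay lower, with adjusted p of 0.339, 0.477, 0.441, 0.339, 0.441, 0.477, 0.339, 0.716 and 0.62 with an estimated correlation, so that 0 of these 14 calls held there. Leaving out 1 array ended 7 of them: DNA replication without WT-Ctrl replicate 3 (adjusted p = 0.122), the mitochondrial ribosome without WT-Ctrl replicate 2 (0.713), complex III without WT-NMyc replicate 2 (0.12), cytosolic ribosomal proteins without WT-NMyc replicate 1 (0.0792), and monocytes (0.665), the TCA cycle (0.11) and complex V (0.0922) without Hom-Ctrl replicate 2. Complexes I, III, IV and V differed more between Hom and WT with Ctrl than with NMyc. Their medians of Hom minus WT were 0.24, 0.37, 0.32 and 0.31 with Ctrl, and 0.06, 0.09, 0.02 and 0.11 with NMyc. For the TCA cycle the medians were 0.36 and 0.19. In Het the ATF4 list (0.32), p53 targets (0.27) and serine, one-carbon and glutamine (0.19) lay higher than in WT and sterol synthesis (-0.15) lower, each with adjusted p = 0.986 with an estimated correlation. Calls were lost for p53 targets without Het-Ctrl replicate 3 (adjusted p = 0.319), serine genes without WT-Ctrl replicate 3 (0.606) and sterol synthesis without WT-NMyc replicate 2 (0.391). Of 100 splits of the arrays within genotypes, only the real one (1) gave as many calls for the averaged NMyc effect, 7470 against 4956 at most in the others. This argues against chance as far as 100 splits can tell. The splits did not keep to the code runs, so they do not address a grouping by run. For Het minus WT with Ctrl the 10 splits are too few for a share under 0.05, and all 10 gave 0 calls, as did the real one. Any split gives at least 0 calls, so this test could not come out otherwise.

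Hom-Ctrl replicate 1 read 9.77 for Mycn, between the other Ctrl arrays and the NMyc arrays. To look for a fault of the whole array, probe sets more than 1.5 log2 units from the other Ctrl arrays were counted. It had 21, against 3 to 21 in the WT and Het arrays and 63 in Hom-Ctrl replicate 2. The other run 1 arrays had 5 (WT-Ctrl) and 4 (Het-Ctrl). The count is within the range of the other arrays but ties the highest of WT and Het, so it does not decide. Admixture of NMyc-transduced cells or their RNA is another candidate explanation: a share of 14.5% would give this Mycn value and raise 1858 probe sets by a median of 0.16. Against the other run 1 arrays they were raised by 0.09, which is 0.591 of the expected shift (95% bootstrap interval 0.481 to 0.674), where WT and Het arrays of the same number differed by up to 0.08. The bootstrap intervals resample probe sets of single arrays and do not measure the spread between arrays. The probe sets were chosen against WT-Ctrl and Het-Ctrl arrays that also serve as the baseline, which can raise the shift. Hom-Ctrl replicate 2, with ordinary Mycn, was raised by 0.27 against its run, and compared with it the shift was -0.18, or -1.16 of the expected (95% bootstrap interval -1.27 to -1.06; up to 0.17 between WT and Het arrays), so admixture cannot be told apart from a property of the genotype or of that culture.

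The 3 Ctrl arrays of run 1 gave Eif2s3y, a Y-linked gene, at 3.59 to 3.96, while the other 11 arrays gave 8.23 to 9.78. Kdm5d and Uty separated the same way, so run 1 may come from female mice, which no label states and no test here addresses. Run 1 as the origin of the NMyc calls is argued against by the 85.8% of calls for the averaged effect that stayed called in the same direction without run 1. Run 1 as sole carrier of the Hom minus WT difference with Ctrl is argued against by r = 0.30 across probe sets between the differences of runs 1 and 2. A part of either result that goes with the sex or handling of run 1 stays open.

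Hom minus WT had 868 calls with Ctrl and 0 with NMyc. Fewer arrays with NMyc as the whole reason are argued against for 283 probe sets that differed by at least 1 log2 unit in run 1: in the other arrays their mean difference in that direction was 0.83 with Ctrl and 0.07 with NMyc, 0.76 apart (95% interval over arrays 0.54 to 0.99), but this rests on Hom-Ctrl replicate 2, the array furthest from the others. With 699 probe sets chosen on run 2, so that Hom-Ctrl replicate 1 is measured, the values were 0.48 and 0.27, which is 0.22 apart (0.1 to 0.33). Each choice leaves a lone Hom-Ctrl array, assumed to vary like the others. Both choices were made on Ctrl differences, so a genotype difference particular to NMyc cells could not enter. Across probe sets, Hom minus WT correlated at 0.38 between runs 2 and 3 with NMyc and at 0.30 between runs 1 and 2 with Ctrl. Fewer arrays may be part of the reason. Fewer neutrophil-lineage cells in Hom-Ctrl, raising all else alike, would leave no marker of other types down. Among 121 such markers 5 were called down and 10 up. These counts were smaller without Hom-Ctrl replicate 2. Mast cell markers shifted 0.56 above monocyte markers (95% interval over arrays 0.21 to 0.9), and 0.26 without Hom-Ctrl replicate 2. The marker calls belong to the comparison to be explained, and the 2 lists had already been called up and down in it. Neither the calls nor the gap are thus separate evidence, and they do not decide. Changes in several cell types stay open. A response to N-Myc that differs between the genotypes stays open, and neither a biological mechanism nor the upstream normalization was tested.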

How the results depend on the processing

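Leaving out only the AFFX controls was chosen after seeing the data. Across the alternatives 0 of the calls reversed direction, but 2 medians of the monocyte list changed sign where its call was lost, without Hom-Ctrl replicate 2: that of Hom minus WT with Ctrl from -0.11 to 0.01, and that of the difference of effects from 0.07 to -0.06. Of the gene values, 16023 stayed on their side of the threshold, 1026 were no longer past it and 1 was newly past it; for lists, 3690 and 318. The numbers pair the arrays of WT-Ctrl and Het-Ctrl alone; other groups share 2 numbers, with correlations of deviations of -0.13 to 0.19. With the replicate number as a block, calls were 7678 for the averaged effect and 653 for Hom minus WT with Ctrl, and Hom minus WT with NMyc gained 1; no other of the 12 counts moved by more than 1.5 times. With runs 2 and 3 alone, NMyc in Hom gave 2597 and Hom minus Het with Ctrl 354, where fewer arrays enter. Hom-Ctrl replicate 2 is then the lone Hom-Ctrl array, assumed to vary like the other groups. Without 8903 dim probe sets the difference of NMyc effects between Hom and WT gave 31, where fewer are tested. Limma's trend and robust options gave 884 for Hom minus Het with Ctrl, 1 for Hom minus WT with NMyc and 62 for the difference of effects; the cause was not tested. With only AFFX controls left out, counts were 442 (Hom minus WT with Ctrl), 231 (Hom minus Het with Ctrl) and 5 (difference of effects), and the mean r between genotypes was 0.744, where more probe sets are tested. List calls fell from 167 to 40 with an estimated correlation, which widens the test's spread. Fry, which asks another question, did not give 40 of the 167 calls; it called 13 lists for Hom minus WT and 10 for Hom minus Het with Ctrl, 1 for Hom minus WT with NMyc, 2 for the difference of effects of Hom and WT, and 0 for Het minus WT with Ctrl, where camera called 4. Leaving out each array in turn gave 6648 to 7710 (averaged effect), 2380 to 4287 (WT), 2490 to 4535 (Het), 1987 to 4228 (Hom), 0 to 0 (Het minus WT, either vector), 99 to 928 (Hom minus WT with Ctrl), 55 to 641 (Hom minus Het with Ctrl), 0 to 0 (Hom minus WT with NMyc), 0 to 1 (Hom minus Het with NMyc), 0 to 0 and 0 to 33 (effects of Het and Hom minus WT), 0.772 to 0.814 (r) and 159 to 174 (list calls). The contrast of positive over negative control sets, 3.605 to 4.521, limits small changes of dim genes.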

Other observations

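Both tests in this part, of a shift toward the NMyc profile and of mitochondrial transcripts, were chosen only after the result was seen. Single members of lists that were not called differed between Hom-Ctrl and WT-Ctrl cells. In the interferon list (2 of 30 members up, adjusted p = 0.217) Bst2, an antiviral membrane protein, rose by 1.3 (SE 0.14, adjusted p = 0.000377). In the apoptosis list (2 of 24 down, adjusted p = 0.752) Bcl2a1b fell by 1.58 (SE 0.20, adjusted p = 0.000846) and Bcl2a1a by 1.49 (SE 0.29, adjusted p = 0.0101), the latter not without Hom-Ctrl replicate 2 (adjusted p = 0.16). Bcl2a1a and Bcl2a1b are copies of the same gene, so their falls may not be separate evidence. Inflammatory genes split: Il1b rose by 1.25 and Il1a, not above the negative control sets in WT-Ctrl, by at least 0.96, while Ccl2 and Ccl7, which attract monocytes, fell by 1.14 and by 1.03 (list adjusted p = 0.665). The Hom-Ctrl arrays (n = 2) lay far apart for these genes, with SDs of 0.75 (Il1b), 0.73 (Il1a), 1.02 (Ccl2) and 0.79 (Ccl7). The sizes therefore depend on single arrays.

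Single members rose with NMyc where their list was called down or was not called. Ms4a2, the beta chain of the IgE receptor of mast cells, rose by 0.95 in WT (SE 0.18, adjusted p = 0.00117) and by 1.10 in Het (SE 0.18, adjusted p = 0.000356), where the mast cell list fell with medians of -0.51 (adjusted p = 0.0513 with an estimated correlation) and -0.34 (adjusted p = 0.101 with an estimated correlation). Alox15, a lipoxygenase of the eosinophil list, rose by 1.88 in Het, where the list was called down (adjusted p = 0.00968, and adjusted p = 0.0582 with an estimated correlation), and by 1.41 in Hom, where it was not called (adjusted p = 0.129). Phlda3 rose by 1.31 in Het (SE 0.20, adjusted p = 0.000199), where the p53 list was not called (adjusted p = 0.895).

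The Hom-Ctrl arrays may lie nearer to the NMyc profile than WT-Ctrl arrays do. Across probe sets, Hom minus WT with Ctrl correlated with the NMyc effect in Het, which shares no array with it, at r = 0.19. Between single runs the value was 0.11, 0.16 and 0.30, while Het minus WT with Ctrl gave 0.01 and -0.07 against the NMyc effect in Hom. Probe sets are not independent replicates, and differences in quality between arrays could give such a correlation too.

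Lower levels of mitochondrial transcripts in Hom cells were looked for, since Polg encodes the polymerase that copies mtDNA. The gene table names no gene of mtDNA, but 9 probe sets carry the mitochondrial chromosome in their IDs, a part of the ID that matched the gene table's chromosome for 99.66% of named sets. Their median difference between Hom and WT with Ctrl was -0.04 (95% interval -0.12 to 0.07 from resampled probe sets, and -0.17 to 0.12 for a difference of -0.02 from the spread between arrays). Their mean level of 12.4 lies above the 99th percentile of all values (11.9), where a lower level could be compressed, so this does not decide. With NMyc the medians were -0.21 for Hom minus WT and -0.26 for Het minus WT, and 0 of the 9 were called.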
